A study of Homo sapiens with 4 samples.

How the data were processed

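RNA sequencing libraries of SK-N-BE(2) cells, an established human neuroblastoma line that carries amplified MYCN, were compared between cells given a scramble short hairpin RNA (shRNA) and cells given an shRNA against IRF2BP2. There were 4 libraries in 2 groups, with 2 libraries per group. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, which does not mark the strand of a transcript. The values used here are raw counts per gene as deposited by the authors, with 1 column per library and no pooling. Reads were aligned with HISAT2 version 2.2.0 to the human genome build hg38, per the submitters' processing notes. The read counter and the gene annotation behind the counts are not given in the sources used here. The columns of the control libraries carry the abbreviation NC, which the labels do not spell out. They were taken as the scramble shRNA libraries because the series has 2 groups and the other columns are named for IRF2BP2, and the replicate number in each column name was matched to the number in the sample title.

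The table held 64252 gene rows, of which 28934 had no count in any library, and no row lacked a gene identifier. A symbol was found for 40995 Ensembl identifiers in a table of gene names. Identifiers without a symbol held between 2.40% and 2.59% of the counts of a library and stayed in the library totals and the tests. Gene types, coordinates and exon lengths came from GENCODE release 29 on GRCh38, which held 56591 of the identifiers. Total counts were 34684651 and 30847699 in scramble replicates 1 and 2, and 31871800 and 32082642 in IRF2BP2 shRNA replicates 1 and 2. Within the scramble pair and the IRF2BP2 shRNA pair, the chi-square of the counts per degree of freedom was 7.66 and 5.67, so the replicates differed by more than sampling noise and none was a copy of another. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

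Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with the filterByExpr rule by group, libraries were scaled by the trimmed mean of M values (TMM, factors between 0.996 and 1.00), and the group effect was tested with the quasi-likelihood F-test with robust estimation of the spread. Tests were two-sided, and p-values were adjusted over all 19093 genes tested by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are IRF2BP2 shRNA over scramble shRNA. A standard error is the absolute log2 fold change divided by the square root of the F statistic. Values in CPM, each count relative to its library total, are scaled by TMM and are given as mean ± SD over 2 libraries. The estimated biological coefficient of variation was 9.52%.

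Before the data were examined, 33 gene lists were written, with 975 members, of which 973 matched an identifier, and lists with at least 5 tested members were tested. They covered neuroblastoma cell identity (adrenergic core regulators, catecholamine and chromaffin genes, mesenchymal neuroblastoma genes, neuronal differentiation genes), signalling, growth, the cell cycle, death and stress, metabolism, immune signalling, adhesion, known partners of the IRF2BP family, signs of RNA quality, and markers of other cell types. Each list was tested with camera from limma 3.58.1 on the edgeR object, which compares the genes of a list with all others, with a preset inter-gene correlation of 0.01. The same test with a correlation estimated from the libraries and the fry rotation test were run beside it. Unless another test is named, a list is said to be called where camera with the preset correlation gave an adjusted p under 0.05. For each list the members called are given adjusted over all genes tested and adjusted over the list alone. Some genes stand in several lists, so the 973 entries are 908 distinct genes.

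The genes named in the text were chosen by a rule fixed before the data were examined. It took IRF2BP2 and its paralogs. It also took the 12 largest rises and the 12 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM in a group, and both IRF2BP2 shRNA libraries on the same side of both scramble libraries. From each list it took up to 4 called members with the smallest p. MYCN, ALK, HAND2, GATA3, ISL1, TBX2 and VEGFA were named whatever their result. Some genes that the rule took are not reported here, and no others were put in their place. Genes named outside this rule are marked as chosen after their values were seen. Because strand was not marked, reads of genes that overlap on opposite strands cannot be told apart, and named genes with such a partner are pointed out.

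The procedure was tested on simulated counts of the 19093 genes with 50 genes changed at each of 4 sizes. For the simulated comparison of IRF2BP2 shRNA with scramble, 26% of the genes changed 1.25-fold, 46% at 1.5-fold, 66% at 2-fold and 96% at 4-fold were recovered. With so few genes changed, the threshold on the unadjusted p was stricter than for the real libraries, so these shares do not describe recovery in the real comparison. Of its 137 calls, 20 were unchanged genes, or 14.6%, and 5.09% of the unchanged genes had an unadjusted p under 0.05. Both simulated lists changed 1.5-fold were recovered, and 0 of 28 unchanged lists were called. The simulated genes were drawn independently of each other, so no list held genes that move together. The 0 of 28 therefore does not describe false calls of real lists whose genes move together. Alternatives planned before the data were examined were other scalings (relative log expression, library totals, upper quartile), DESeq2 1.42.0, limma voom, no filter on low counts, a filter at a mean of 10 CPM, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, and a test against a 1.5-fold change. A fit on protein-coding genes and a fit without mitochondrially encoded genes were added after the data had been seen. Scripts outside R used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.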

Results

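The data were RNA sequencing counts from SK-N-BE(2) neuroblastoma cells with a scramble shRNA (2 libraries) or an shRNA against IRF2BP2 (2 libraries). Total counts lay between 30847699 and 34684651 per library. The share of counts from mitochondrially encoded genes was 7.27% and 7.10% in the scramble libraries and 6.42% in each IRF2BP2 shRNA library. The comparison asked which transcripts change when IRF2BP2 is lowered in these cells.

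IRF2BP2, a transcriptional co-regulator first described as a partner of IRF2, lies on chromosome 1 from 234604269 to 234609525 on the minus strand (GRCh38, gene ENSG00000168264). Its level was 243 and 238 CPM in the scramble libraries and 89.6 and 87.6 CPM in the IRF2BP2 shRNA libraries. It was 2.71-fold lower with the shRNA (log2 fold change -1.44, standard error 0.04, edgeR quasi-likelihood adjusted p = 5.87e-10), with both libraries below both scramble libraries. Its paralog IRF2BPL rose from 155 ± 11.4 to 272 ± 6.84 CPM (SD, n = 2), a log2 fold change of 0.81 (edgeR adjusted p = 4.65e-07). The paralog IRF2BP1 had 32.2 ± 2.05 CPM with scramble and 35.6 ± 3.66 CPM with the shRNA, a difference that did not pass the test (edgeR adjusted p = 0.223).

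**Figure D1:**
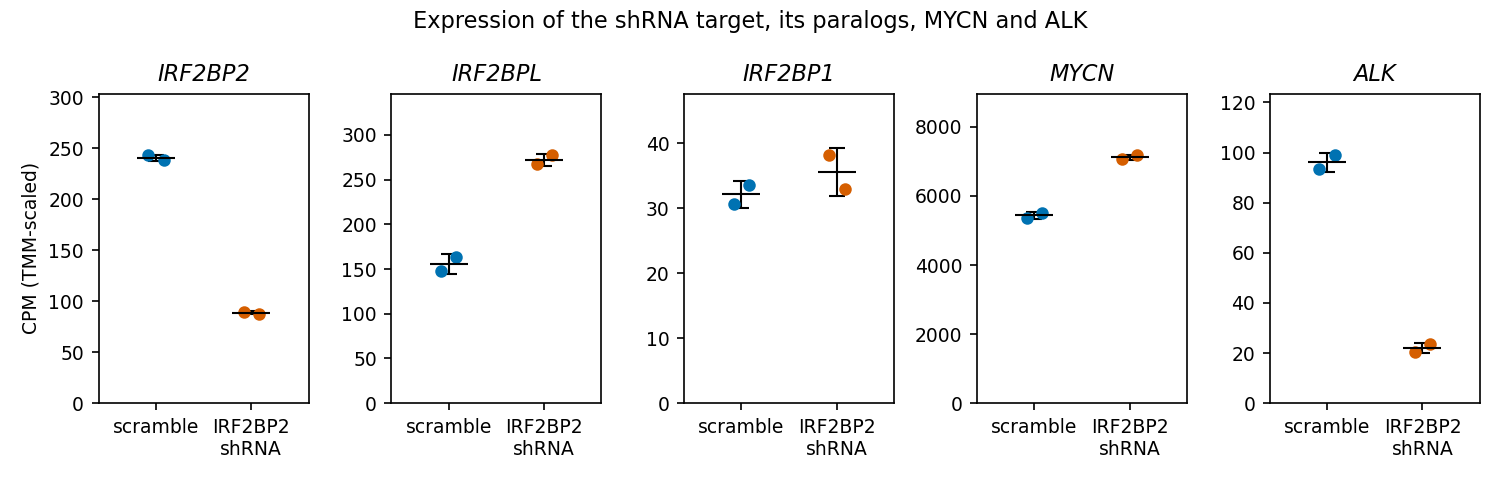
CPM (TMM-scaled, linear axis from 0) of IRF2BP2, IRF2BPL, IRF2BP1, MYCN and ALK in each library, with dots for the 2 libraries of a group, a horizontal line at the mean and bars of 1 SD. IRF2BP2 and ALK were lower in both IRF2BP2 shRNA libraries, IRF2BPL and MYCN were higher, and the IRF2BP1 values of the groups overlapped.

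Lowering of IRF2BP2 came with changes in a large part of the transcriptome. Of 19093 genes tested, 8016 (42.0%) changed, with 3930 higher and 4086 lower. Most changes were small, since 4632 of the changed genes (57.8%) moved by less than 1.5-fold. Among the 1852 genes that changed over 2-fold, 563 were higher and 1289 were lower. Tested against a change of 1.5-fold, 1619 genes passed, with 545 higher and 1074 lower. Of 13734 protein-coding genes tested, 7004 changed. In simulated libraries of this size 14.6% of the calls were unchanged genes, more than the 5% aimed at, where few genes had been changed.

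The genes with the largest rises had low levels with scramble. IGFBP3, which binds insulin-like growth factors, rose from 2.54 ± 0.73 to 97.7 ± 4.69 CPM (SD, n = 2), and APLNR, the apelin receptor, from 2.21 ± 0.54 to 69.1 ± 2.98 CPM. BMP6, a bone morphogenetic protein, rose from 0.18 ± 0.11 to 7.97 ± 0.35 CPM. The log2 fold changes were 5.48 for SMIM32, 5.42 for BMP6, 5.25 for IGFBP3 and 4.95 for APLNR. CHST8 (3.89), GDF15 (3.87), GASK1B (3.85), the transcription factor gene GATA4 (3.78) and the sialomucin gene EMCN (3.74) also rose on the log2 scale. DLX2, a homeobox gene, had a log2 fold change of 4.98 (edgeR adjusted p = 0.00402), but the call was lost without IRF2BP2 shRNA replicate 1 (edgeR adjusted p = 0.0865) or replicate 2 (edgeR adjusted p = 0.0789), while the log2 fold change stayed at 5.02 and 4.94. SAMD11 had a log2 fold change of 4.18, and it overlaps NOC2L on the opposite strand, whose mean count was 7480 against 1508 for SAMD11.

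The largest falls included DBH and GCH1 of the catecholamine list. DBH, the enzyme that turns dopamine into noradrenaline, fell from 63.4 ± 6.85 to 1.72 ± 0.48 CPM (SD, n = 2; log2 fold change -5.20), and GCH1, the first enzyme in the synthesis of the tetrahydrobiopterin cofactor, from 94.3 ± 1.76 to 7.16 ± 0.30 CPM (-3.72). TIMP3, an inhibitor of metalloproteinases, fell from 22.0 ± 3.46 to 0.47 ± 0.09 CPM (-5.54). The others on the log2 scale were PARM1 (-5.16), the proteoglycan gene SPOCK1 (-4.76), FAM163B (-4.29), RIPOR3 (-4.14), the potassium channel gene KCNH1 (-3.90), PRR36 (-3.60), PXDNL (-3.59) and SORBS2 (-3.47). In the 11 rises and the 11 falls named here the edgeR adjusted p lay at or under 0.00402, and both IRF2BP2 shRNA libraries lay on the same side of both scramble libraries.

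**Figure D2:**
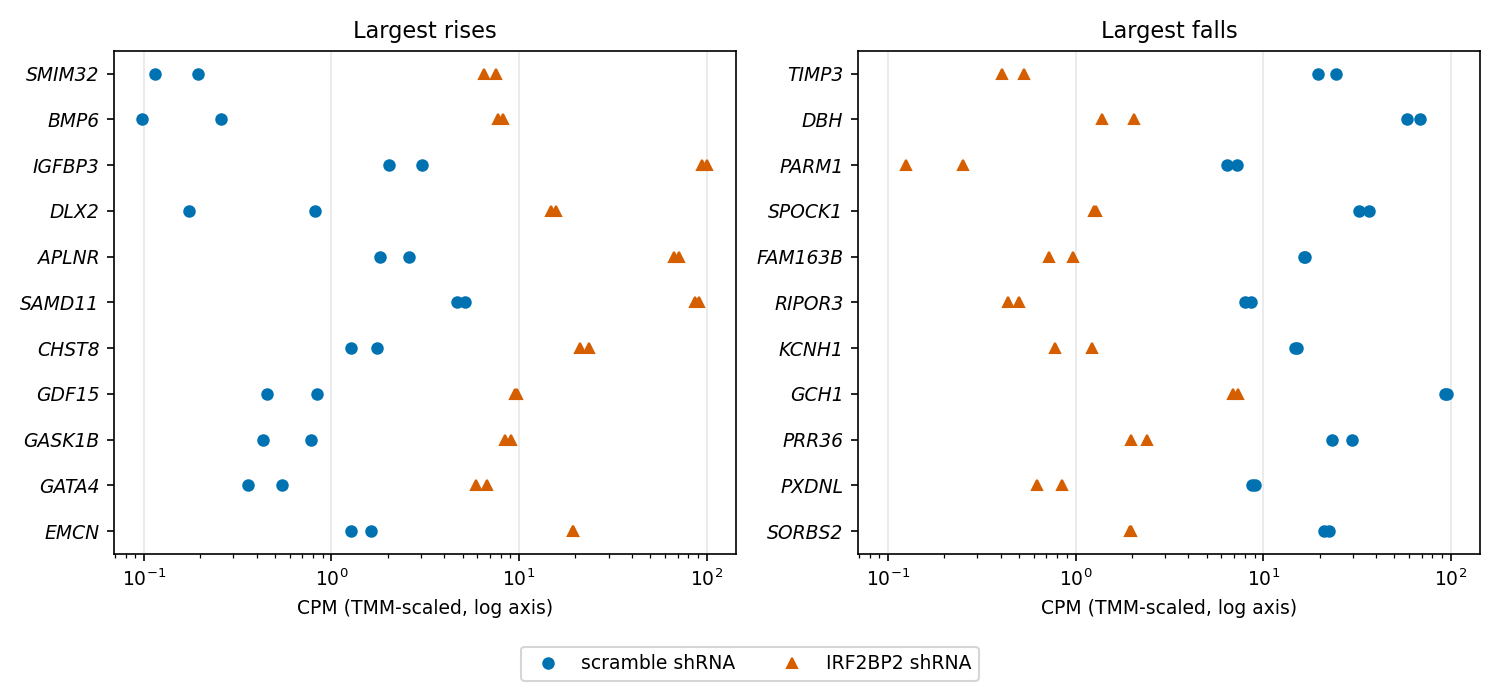
CPM (TMM-scaled, log axis) in each library of 11 of the 12 largest rises (left) and 11 of the 12 largest falls (right), with blue circles for the 2 scramble libraries and orange triangles for the 2 IRF2BP2 shRNA libraries. In all 22 genes the libraries of the 2 groups stand apart, as the rule that chose them required.

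Genes of adrenergic neuroblastoma identity were mostly lower with the IRF2BP2 shRNA. Of 24 adrenergic core regulators, 16 fell, 4 rose and 4 were not called. SIX3 (-1.26), INSM2 (-0.96) and TFAP2B (-0.84) fell on the log2 scale. ISL1 fell by 0.79 and HAND2 by 0.40, and reads of HAND2 cannot be separated from those of its antisense partner HAND2-AS1. GATA3 had a log2 fold change of 0.06 and was not called (edgeR adjusted p = 0.237), while TBX2 (0.50) and MYCN (0.39, from 5439 ± 110 to 7125 ± 70.5 CPM, edgeR adjusted p = 5.09e-07) rose. The list as a whole was lower (camera adjusted p = 1.28e-09; adjusted p = 0.148 with an estimated correlation).

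Catecholamine and chromaffin genes were also mostly lower. Of 22 tested, 15 fell, 3 rose and 4 were not called, with a median log2 fold change of -0.92. Besides DBH and GCH1, the granule protein gene CHGB fell from 301 ± 16.7 to 36.6 ± 1.03 CPM, the neuropeptide gene GAL by 1.54 and the exocytosis gene SNAP25 by 1.77 on the log2 scale (camera adjusted p = 8.03e-28; adjusted p = 0.148 with an estimated correlation). Of 29 neuronal differentiation genes, 21 fell, 6 rose and 2 were not called. STMN2, which binds tubulin in growing axons, fell from 1014 ± 17.5 to 255 ± 1.75 CPM, and the cell adhesion genes CNTN1 (-1.92) and L1CAM (-1.49) fell, while PLXNA4, a semaphorin receptor gene, rose 10.8-fold (camera adjusted p = 2.34e-13 for the list, lower; adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone, the counts were 4 higher and 17 lower for the adrenergic list, 3 higher and 16 lower for the catecholamine list, and 6 higher and 21 lower for the neuronal list.

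Mesenchymal neuroblastoma genes moved both ways, with 11 of 27 higher, 8 lower and 8 not called, and the list was not called (camera adjusted p = 0.161). By fry, which does not compare a list with other genes, the list was higher (fry adjusted p = 0.0104). Its members SNAI2 (1.87), FN1 (1.08) and VIM (0.56) rose on the log2 scale. Adjusted over the list alone, 11 were higher and 10 lower, and with a mean of at least 10 CPM 6 were higher and 7 lower. Among 21 receptor tyrosine kinase genes, 5 rose, 12 fell and 4 were not called (camera adjusted p = 0.0852; adjusted over the list alone 6 higher and 13 lower; without IRF2BP2 shRNA replicate 2 camera adjusted p = 0.0267). The receptor tyrosine kinase list was lower by fry (fry adjusted p = 0.0164). ALK, a receptor often mutated in neuroblastoma, fell from 96.1 ± 3.82 to 22.0 ± 2.06 CPM (edgeR adjusted p = 2.71e-09) and ROR2 by 0.61 on the log2 scale, while EPHA2 (1.35) and FGFR1 (0.56) rose.

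**Figure D3:**
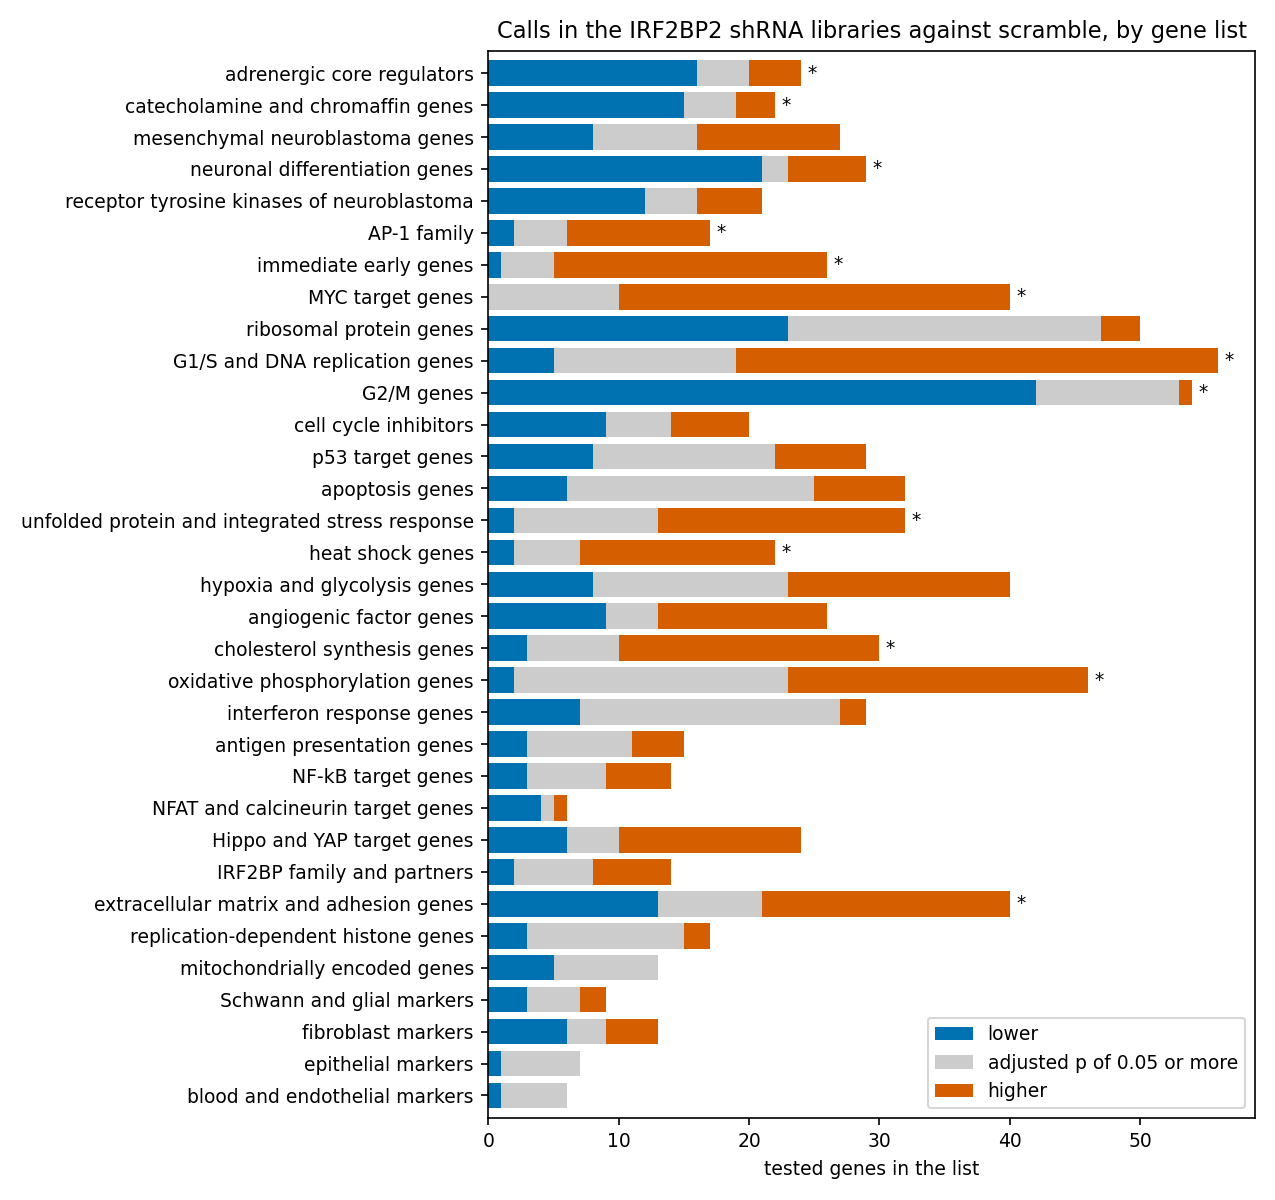
Number of tested genes in each of the 33 lists that were lower (blue), not called (grey) or higher (orange) in the IRF2BP2 shRNA libraries against scramble (edgeR adjusted p under 0.05). An asterisk marks the 13 lists called by camera with the preset correlation, of which 9 were higher and 4 lower; none was called with an estimated correlation.

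Immediate early genes and the AP-1 family were higher. The lists share members, JUNB among them, so their results are not independent. Of 26 immediate early genes, 21 rose, 1 fell and 4 were not called. EGR1 rose from 21.4 ± 2.08 to 86.6 ± 0.44 CPM, and SPRY2 (1.44) and SPRY4 (0.64), inhibitors of receptor tyrosine kinase signalling, rose on the log2 scale, while DUSP6, a phosphatase of ERK, fell by 0.88 (camera adjusted p = 1.89e-08, higher; adjusted p = 0.148 with an estimated correlation). Of 17 AP-1 family genes, 11 rose, 2 fell and 4 were not called. JUND (1.04), JUNB (1.01) and MAFG (0.57) rose, and JUNB overlaps HOOK2 on the opposite strand, while MAFG shares part of its locus with SIRT7 (camera adjusted p = 4.50e-06, higher; adjusted p = 0.148 with an estimated correlation). The counts adjusted over the list alone were the same for both lists.

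Most of the MYC target and G1/S genes listed were higher, and most of the G2/M genes were lower. Of 40 MYC target genes, 30 rose, 0 fell and 10 were not called, with a median log2 fold change of 0.24. The rises included the ribosome biogenesis gene PES1 (0.64), the polyamine enzyme genes ODC1 (0.57) and SRM (0.57) and MCM5 (0.68), which also stands in the G1/S list (camera adjusted p = 1.89e-08, higher; adjusted p = 0.148 with an estimated correlation). Of 56 G1/S and DNA replication genes, 37 rose, 5 fell and 14 were not called, with CDC6 (0.56), MCM10 (0.54) and UNG (0.49) among the rises (camera adjusted p = 5.52e-06, higher; adjusted p = 0.406 with an estimated correlation). Of 54 G2/M genes, 42 fell, 1 rose and 11 were not called. TOP2A fell from 837 ± 3.40 to 516 ± 11.7 CPM, CDK1 from 221 ± 7.30 to 129 ± 0.41 CPM, and HMGB2 (-0.67) and DLGAP5 (-0.70) fell on the log2 scale (camera adjusted p = 2.34e-13, lower; adjusted p = 0.148 with an estimated correlation). Adjusted over the list alone, 30 MYC targets were higher and 0 lower, 39 G1/S genes higher and 5 lower, and 1 G2/M gene higher and 45 lower.

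**Figure D4:**
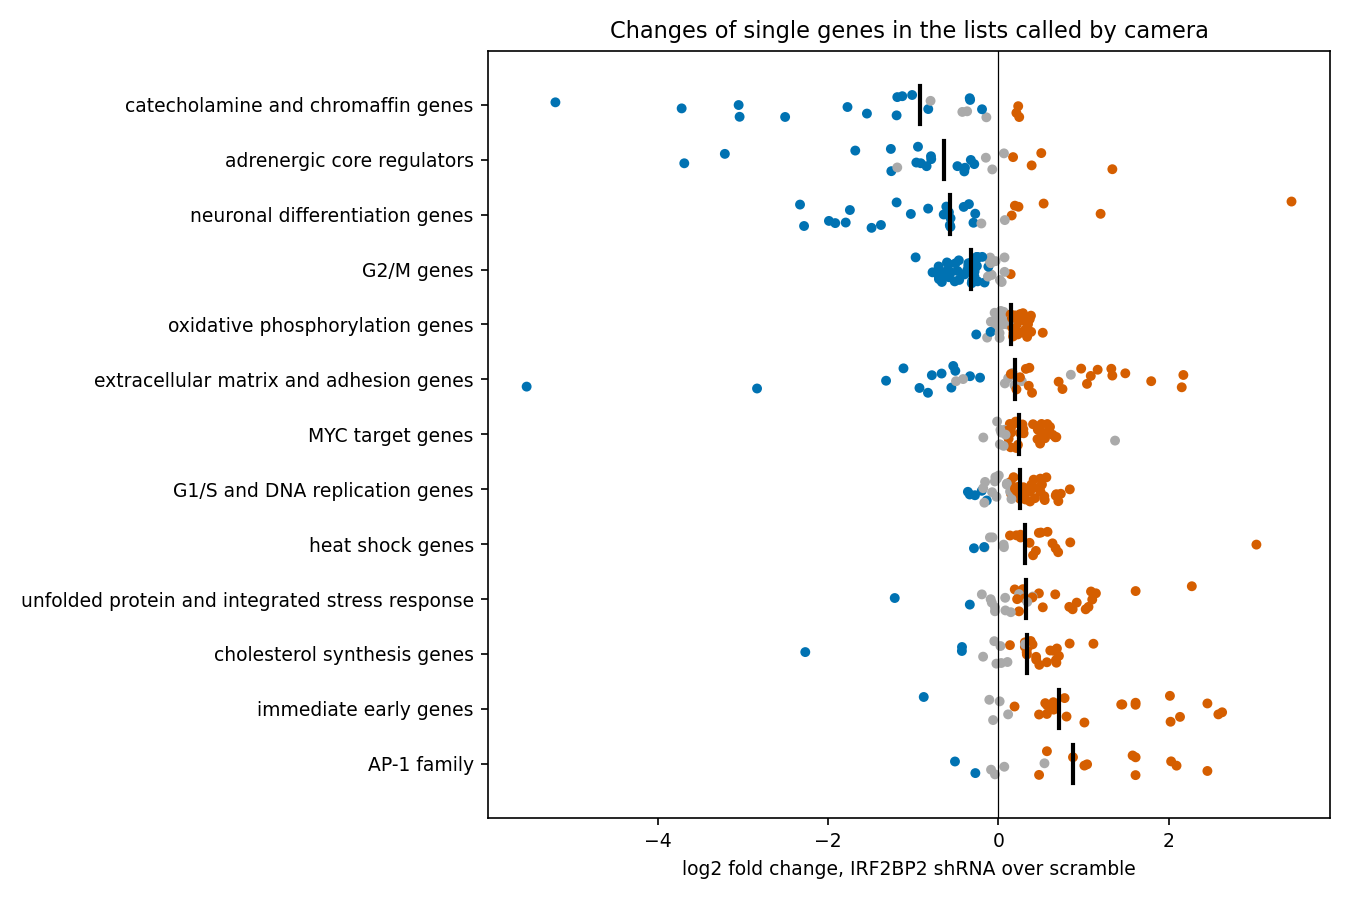
Log2 fold change (IRF2BP2 shRNA over scramble) of every tested gene in the 13 lists called by camera, with orange for genes called higher, blue for genes called lower, grey for genes not called and a black line at the list's median. The median was -0.92 for catecholamine and chromaffin genes, 0.87 for the AP-1 family and 0.71 for immediate early genes; with a mean of at least 10 CPM the last 2 were 0.48 and 0.53.

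Ribosomal protein genes were not called as a list (camera adjusted p = 0.161), with 3 of 50 higher, 23 lower and 24 not called and the same counts adjusted over the list alone. RPL3 (-0.42) and RPL13 (-0.43) fell on the log2 scale. The list was called lower without scramble replicate 1 (camera adjusted p = 1.71e-05), and in 3 of 13 alternative settings in all. Its counts hung on single libraries, with 1 higher and 32 lower without scramble replicate 1, 14 and 16 without scramble replicate 2 (camera adjusted p = 0.609), 2 and 12 without IRF2BP2 shRNA replicate 1, and 0 and 15 without replicate 2. Cell cycle inhibitor genes had 6 higher, 9 lower and 5 not called of 20 (camera adjusted p = 0.418, with the same counts adjusted over the list alone). Fry gave this list as lower (fry adjusted p = 0.0448). TXNIP (-1.09) and RB1 (-0.61) were lower and BTG3 (0.83) higher. The median of the list was -0.05 and its mean 0.06. Its median lay between -0.20 and 0.04 in 13 alternative settings and changed sign in 1.

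Genes of the unfolded protein and integrated stress response, protein folding and cholesterol synthesis were higher. Of 32 stress response genes, 19 rose, 2 fell and 11 were not called. The amino acid transporter genes SLC7A11 (2.27), SLC7A5 (1.14) and SLC3A2 (1.06) rose on the log2 scale, while VLDLR, a lipoprotein receptor gene, fell by 1.22 (camera adjusted p = 1.35e-08, higher; adjusted p = 0.148 with an estimated correlation). Of 22 heat shock genes, 15 rose, 2 fell and 5 were not called, with CHORDC1 (0.58) higher and HSP90AB1 (-0.29) lower (camera adjusted p = 5.53e-04, higher; adjusted p = 0.195 with an estimated correlation). Of 30 cholesterol and fatty acid synthesis genes, 20 rose, 3 fell and 7 were not called. CYP51A1 (0.69) and FASN (0.61) rose on the log2 scale (camera adjusted p = 1.21e-07, higher; adjusted p = 0.148 with an estimated correlation). Adjusted over the list alone, 20 stress response genes were higher and 2 lower, 15 heat shock genes higher and 2 lower, and 21 cholesterol genes higher and 3 lower.

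Oxidative phosphorylation genes encoded in the nucleus had 23 of 46 higher, 2 lower and 21 not called, the same adjusted over the list alone, with UQCRH (0.35) and ATP5MC1 (0.38) among the rises. The list was called higher (camera adjusted p = 0.0187; adjusted p = 0.633 with an estimated correlation), in 10 of 13 alternative settings but not, for instance, with upper quartile scaling (camera adjusted p = 0.0595) or a mean of at least 10 CPM (camera adjusted p = 0.144), and without IRF2BP2 shRNA replicate 2 the counts were 15 higher and 1 lower. By fry the oxidative phosphorylation list was not called (fry adjusted p = 0.0636). Mitochondrially encoded genes had 0 of 13 higher, 5 lower and 8 not called, with the same counts adjusted over the list alone. MT-CO1 (-0.29) and MT-CO3 (-0.36) were lower. Their list was not called by camera (camera adjusted p = 0.418) but was lower by fry (fry adjusted p = 0.0150). Without scramble replicate 2 there were 2 higher and 6 lower. The median of the mitochondrially encoded genes was close to 0 and changed sign in 2 of 12 alternative settings. Hypoxia and glycolysis genes moved both ways, with 17 of 40 higher, 8 lower and 15 not called (camera adjusted p = 0.0875; the same counts adjusted over the list alone; called higher in 3 of 13 alternative settings, which were no filter on low counts, camera adjusted p = 0.00408, limma voom, 0.0179, and without scramble replicate 2, 0.0302). The hypoxia and glycolysis list was higher by fry (fry adjusted p = 0.0493). ADM, a vasodilator peptide gene, fell from 29.4 ± 3.38 to 2.94 ± 0.35 CPM, while the glycolysis genes ALDOA (0.64) and PFKFB3 (0.76) rose. Of 26 angiogenic factor genes, 13 rose, 9 fell and 4 were not called (camera adjusted p = 0.785; the same counts adjusted over the list alone). With a mean of at least 10 CPM the direction of this list turned to lower, with 5 higher and 5 lower and a median log2 fold change of -0.09 in place of 0.37, and the median was 0.04 without IRF2BP2 shRNA replicate 1. VEGFA rose from 41.4 ± 0.12 to 72.5 ± 1.10 CPM (edgeR adjusted p = 7.25e-07), while NRP2 (-1.57) and ANGPT1 (-2.44) fell.

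Extracellular matrix and adhesion genes had 19 of 40 higher, 13 lower and 8 not called (20 higher and 13 lower adjusted over the list alone). COL5A1 (1.79), SPARC (0.97) and MMP2 (0.75) rose on the log2 scale while TIMP3 fell. The list was called higher (camera adjusted p = 0.0197; adjusted p = 0.334 with an estimated correlation), but the call was lost without scramble replicate 1 (0.0676), without scramble replicate 2 (0.0748) and without IRF2BP2 shRNA replicate 1 (0.0860), as camera adjusted p, and it held in 7 of 13 alternative settings. Hippo and YAP target genes had 14 of 24 higher, 6 lower and 4 not called (15 higher and 7 lower adjusted over the list alone). CCN1 (1.85) rose and NT5E (-2.48) fell (camera adjusted p = 0.0551). The list was called higher in 6 of 13 alternative settings, for instance without scramble replicate 1 (camera adjusted p = 0.00830) or without IRF2BP2 shRNA replicate 2 (0.0198, with 11 higher and 2 lower), but with a mean of at least 10 CPM its direction turned to lower (camera adjusted p = 0.913), with 4 genes higher and 5 lower and a median log2 fold change of -0.06 in place of 0.50. Of 14 IRF2BP family members and partners, 6 rose, 2 fell and 6 were not called (6 higher and 3 lower adjusted over the list alone), with RBFOX2 (-0.60) lower (camera adjusted p = 0.144). Fry gave this list as higher (fry adjusted p = 0.0368).

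Lists of death and immune genes were not called by camera. By fry the interferon response (fry adjusted p = 0.0261) and NFAT and calcineurin (fry adjusted p = 0.0216) lists were lower. The antigen presentation list was higher by fry (fry adjusted p = 0.0472). The p53 targets had 7 of 29 higher, 8 lower and 14 not called (camera adjusted p = 0.595; 6 higher and 5 lower without IRF2BP2 shRNA replicate 1), with AEN (0.67) higher and PMAIP1 (-1.23) lower. Apoptosis genes had 7 of 32 higher, 6 lower and 19 not called (camera adjusted p = 0.785), with MCL1 (-0.60) lower. Their median was 0.04 and their mean -0.01, and the median changed sign in 3 of 13 alternative settings (-0.03 to 0.06). Interferon response genes had 2 of 29 higher, 7 lower and 20 not called (camera adjusted p = 0.310, but 0.0456 with a mean of at least 10 CPM), with OAS3 (-1.17) and UBE2L6 (-0.58) lower. Antigen presentation genes had 4 of 15 higher, 3 lower and 8 not called (camera adjusted p = 0.595; 2 higher and 1 lower without IRF2BP2 shRNA replicate 1, 2 and 0 without replicate 2), with CALR (0.52) and B2M (0.21) higher. NF-kB targets had 5 of 14 higher, 3 lower and 6 not called (camera adjusted p = 0.901; between 2 and 5 higher in the alternative settings), with NFKB1 (0.59) higher and CYLD (-0.86) lower; their median was 0.16 and their mean -0.04. Of 6 NFAT and calcineurin targets tested, 1 rose, 4 fell and 1 was not called (camera adjusted p = 0.148), with NFATC4 (-0.48) and RCAN1 (-0.42) lower. The median was -0.32 and the mean 0.04, and the median lay between -0.40 and -0.10 in 12 alternative settings. In each of these 6 lists the counts adjusted over the list alone were the same.

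Markers of other cell types gave no called list. A mean of at least 5 CPM was reached by 4 of 9 Schwann and glial and 10 of 13 fibroblast markers. It was reached by 0 of 7 epithelial and 1 of 6 blood and endothelial markers, so lists of such low genes could hardly be called. By fry the Schwann and glial list (fry adjusted p = 0.0114) and the epithelial list (fry adjusted p = 0.0318) were lower. Schwann and glial markers had 2 of 9 higher, 3 lower and 4 not called (camera adjusted p = 0.358), with PMP22 (-0.79) lower; no marker was called higher without IRF2BP2 shRNA replicate 1 or without replicate 2, and the median turned from -0.30 to 0.07 without replicate 1. Fibroblast markers had 4 of 13 higher, 6 lower and 3 not called (camera adjusted p = 0.785; 4 higher and 7 lower adjusted over the list alone), with COL1A1 (2.17) and COL3A1 (1.49) higher and LUM (-1.03) and PDGFRA (-1.24) lower; their median was -0.36 and their mean 0.08. Of 7 epithelial markers 1 was called, EPCAM (-0.90), which lost its call without IRF2BP2 shRNA replicate 1 (edgeR adjusted p = 0.0752; list camera adjusted p = 0.573). Of 6 blood and endothelial markers 1 was called, PTPRC (-0.87), which lost its call without scramble replicate 2 or IRF2BP2 shRNA replicate 2 (list camera adjusted p = 0.915). The list's median was -0.01 and its mean 0.01. Its median was not stable, lying between -0.85 and 0.05 in 12 alternative settings with a change of sign in 3. Replication-dependent histone genes had 2 of 17 higher, 3 lower and 12 not called (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.803; 1 higher and 1 lower without IRF2BP2 shRNA replicate 2). The histone list was lower by fry (fry adjusted p = 0.0318). The examples H2AC11 (0.80) and H2AC6 (-0.82) were not stable. H2AC11 lost its call without IRF2BP2 shRNA replicate 1 (edgeR adjusted p = 0.169), and H2AC6 without scramble replicate 1 (edgeR adjusted p = 0.0929) or IRF2BP2 shRNA replicate 2 (edgeR adjusted p = 0.0928). Except where given, the counts adjusted over the list alone were the same.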

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

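The number of genes changed over 2-fold was 509 of 10383 tested with a filter at a mean of 10 CPM, against 1852 of 19093. This drop was larger than that in the number of genes tested. Changes over 2-fold were thus more frequent among genes with a lower mean. Against a 1.5-fold change 1619 genes passed in place of 8016, because the null hypothesis was wider. The number of gene lists called was 0 with an estimated inter-gene correlation in camera and 24 with fry, against 13. With the estimated correlation 8 lists had an unadjusted p under 0.05, and fry does not compare a list with other genes. Of the called lists, the estimate lay below the preset 0.01 for the AP-1 family (-0.06), immediate early (-0.04) and heat shock (-0.04) lists. The same held for the MYC target (-0.02), cholesterol synthesis (-0.03) and extracellular matrix (0.008) lists. A stronger correlation than the preset thus does not account for the lost calls of these lists. For the other called lists the estimate lay between 0.02 and 0.14. Leaving out each library gave between 6412 and 7478 changed genes, an IRF2BP2 level between -1.4542 and -1.419 as a log2 fold change, and between 13 and 15 lists, with the lone library assumed to vary like the other group. DESeq2 called 6471 genes, of which 6404 were shared with edgeR in the same direction. With upper quartile scaling 41.8% of the called genes were higher, against 49.0%, and the median of all genes moved by -0.05. Of 138 named genes besides IRF2BP2, 127 kept their direction and their side of the threshold in every setting that tested them, and none changed direction. The 11 that lost a call in at least 1 setting were GAP43, HLA-C, TAP1, H2AC6, H1-4, EPCAM, H2AC11, H2BC11, NGFR, PTPRC and DLX2. Most named genes were chosen for a large change or a small p in these same libraries, so their stability follows in part from the choice. It does not describe the stability of all called genes. With protein-coding genes alone, an alternative chosen after seeing the data, 7365 genes and 11 lists were called, and without mitochondrially encoded genes, also chosen then, 8011 genes and 14 lists. In simulated data with few genes changed, 26% of the genes with the smallest change were recovered, so small changes can be missed in such a setting. With many genes called, as in the real comparison, the threshold on the unadjusted p is less strict. The share of small changes missed in the real comparison is therefore not known.

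The titles share replicate numbers, but with 2 pairs and no label that ties a number to a day, the samples share only a number. The deviations of same-numbered libraries correlated at 0.06. With the replicate block 7900 genes were called, of which 7627 were shared with the fit without it, and 13 lists.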

Other observations

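Further gene groups were written down after the main results had been seen, though the values of their members had not been looked at unless stated. Of 23 synaptic vesicle genes tested, 17 were lower, 2 were higher and 4 were not called. CPLX2, which controls vesicle fusion, fell from 243 to 97.53 CPM, and the synapsin genes SYN1 (-0.83) and SYN2 (-0.56) fell on the log2 scale, while SV2A (0.40) and SV2C (0.53) rose. Random lists matched on expression had a median of 5 lower genes, and the share with as many was 0.0001, the smallest that 10000 draws can give. The random genes were drawn one by one, so this share takes no account of genes that move together and may be too small. HOX genes gave a negative result, with 4 of 12 lower and 0 higher (random median 3, share 0.317). The genes named here were chosen after their values were seen.

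Target and pathway genes of BMP and TGF-beta were noticed among the rises. ID1 (2.92), ID2 (2.72), ID3 (2.02), SMAD6 (2.61), BAMBI (2.09) and MSX2 (3.06) rose on the log2 scale, and all 14 genes of this kind that had been looked at were higher, which is no test since they were picked by their values. Higher BMP or TGF-beta signalling may account for this, and among 17 further genes not looked at before, 10 were higher and 3 lower (random median 4, 95th percentile 7, share 0.0026). The median log2 fold change of these 17 was 0.32, against 2.24 for the 14 picked genes. SMAD3 (0.03), PMEPA1 (-0.04), TGIF1 (-0.20) and LTBP1 (-0.27) were the 4 not called. As the list joins genes of both pathways, its count cannot tell BMP from TGF-beta signalling. The 3 lower genes were TGFBR1 (-1.02), ACVRL1 (-0.48) and LTBP2 (-1.04), the first 2 being receptor genes, and the ligand genes BMP4 (-1.58) and BMP7 (-1.39) fell while BMP6 rose. Higher NRF2 activity may likewise account for the rise of OSGIN1 (3.39), AKR1C1 (2.84), AKR1C3 (2.85) and SLC7A11 (2.27), since 16 of 25 NRF2 targets not looked at before were higher and 5 lower (random median 8, 95th percentile 11, share 0.0004). The rises included NQO1 (1.31) and FTH1 (0.69), but HMOX1 (-0.27), TXNRD1 (-0.12), TXN (-0.14), TALDO1 (-0.17) and FECH (-0.57) fell. GCLM (-0.03) and ME1 (-0.05) were among the 4 not called. SLC7A11 also stands in the stress response list that was called higher. The counts of the aldo-keto reductase family as a whole, which holds AKR1C2, had been seen before. Without AKR1C2, 15 of 24 were higher and 5 lower (random median 7, 95th percentile 11, share 0.0014). Genes of the random lists were drawn one by one, so the shares given here take no account of targets that move together and may be too small. Voltage-gated sodium channel genes, which had been looked at before, had 7 of 10 lower and 0 higher, which is no test. A fall of excitability genes at large could not be decided, since 8 of 23 calcium and potassium channel genes not looked at before were lower and 4 higher (random median 5, 95th percentile 8, share 0.102).

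The tests of MYCN, of the number of shRNA labels and of fewer dividing cells were chosen after their results had been seen; the others were written before. The fall of adrenergic, catecholamine and neuronal genes could come from GC content or length bias, but after removal of that trend the median log2 fold change of the 3 lists together was -0.67 (95% bootstrap interval -0.90 to -0.44, 70 of 75 members with values). The bootstrap resampled the genes of the lists one by one, not the libraries. Its interval holds no spread between libraries, takes no account of genes that move together and may be too narrow. Cells without MYCN amplification in the IRF2BP2 shRNA libraries would lower MYCN as well if its level in the other cells were unchanged. The log2 fold change of MYCN was 0.39. As this value had been seen first, it is no test, and a rise of MYCN in the other cells could hide such a dilution. An off-target effect of the shRNA or a culture difference between the arms cannot be told apart from lower IRF2BP2, since the series has 1 IRF2BP2 shRNA label. A loss of adrenergic identity on lowering of IRF2BP2 remains a hypothesis beside it. Its test, that a further IRF2BP2 shRNA with another sequence would lower the 3 lists, was not run, as no such library was analysed here.

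The opposite moves of G1/S and G2/M genes could reflect fewer dividing cells. With transcription per cell unchanged, fewer dividing cells alone would lower both lists. The G1/S median was 0.25 (95% bootstrap interval 0.16 to 0.32) beside a G2/M median of -0.32 (-0.46 to -0.26). All bootstrap intervals in this paragraph resampled genes and not libraries, so they may be too narrow, as above. As the G1/S and G2/M values had been seen first, their comparison is no test. Fewer dividing cells together with a change of transcription cannot be excluded. GC content or length bias was argued against, as the difference of the medians was 0.55 after its removal (0.44 to 0.67) and 0.58 before. A shift of cells between phases of the cycle and a change of transcription within phases stay open, since no measurement of phase was analysed here, and so does the off-target effect or culture difference above.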
